A study of Mus musculus with 12 samples.

How the data were processed

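RNA was sequenced from neutrophils that had been isolated with a magnetic bead kit (MojoSort) from the marrow of mouse femurs and tibias, after 3 h with PBS or UPEC. Per the labels, total RNA was depleted of ribosomal RNA and made into directional libraries with NEBNext kits. The deposited values are raw counts per Ensembl gene, 1 library per file, which the authors made from reads on the mm10 build with Trim Galore 0.6.6, TopHat2 2.1.2, SAMtools 1.15 and HTSeq 0.12.4, with edgeR 3.42.4 also listed. The annotation release and the strand setting are not given in the sources used here. Each file held 43432 gene IDs, of which 42548 received a symbol and position from GENCODE M21, and the 884 others held 0.126% of the counts.

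Total gene counts per library ran from 27312527 to 34884314. Reads outside annotated genes made up 4.295% to 6.641%, ambiguous reads 2.979% to 3.137%, and the 10 most abundant genes 13.437% to 14.992% of the gene counts. A count of 0 allows up to 3 counts per library, which covers counting error only.

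Groups were fixed from the labels as 4 combinations of 2 genotypes and 2 treatments with 3 libraries each. Genes were kept by filterByExpr with its defaults on the groups, which left 13587. Libraries were scaled by TMM, with factors from 0.929 to 1.054, and fitted in edgeR 4.0.16 on R 4.3.3 with 1 coefficient per group, robust quasi-likelihood dispersions and no covariate. Comparisons were UPEC against PBS in each genotype, knockout against wild type with each treatment, and the difference of the responses (interaction). Benjamini-Hochberg adjustment ran over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. The common biological coefficient of variation was 4.5%. Log2 changes carry the standard error of the fit, and CPM values are means with SD over 3 libraries.

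Tests of 37 gene lists, covering pathways, granule proteins and markers of other cells, used camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2. They were repeated with an estimated correlation and with fry, a rotation test. Genes are named by a rule fixed before the data were examined. It takes Cybb, then up to 8 genes with the largest rise and 8 with the largest fall at 5 CPM or more and without overlap of the groups, which the interaction did not require. Genes without a symbol, predicted genes, pseudogenes and mitochondrial genes were left out. It adds up to 4 members per described list with the lowest p, and a fixed panel of inflammatory, granule and oxidase genes.

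Alternatives were RLE size factors, total counts without scaling factors, DESeq2 1.42.0, limma-voom, other filters on low counts, a 2-fold minimum, a test against a 1.2-fold change (glmTreat), the replicate number as a block, fits of 6 libraries alone, removal of mitochondrial genes, and each library left out in turn. Chosen after seeing the data were fits without KO PBS replicate 2 and KO UPEC replicate 3 together, and counts without immunoglobulin and other-cell genes. Other splits of the same libraries were counted for each comparison. The procedure was tested on simulated counts of 13587 genes. At a 2-fold change it recovered 78% to 85% of changed genes in the 2 responses and 72% in the interaction, at 1.2-fold 28% in the interaction, and false calls made up 3.73% to 7.1% of the calls where genes had been changed. Of 36 random lists 0 were called, and a list of 25 genes moved 1.5-fold was called. The simulated genes were drawn independently, so this does not test the preset correlation for lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.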

Results

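Gene expression was measured by RNA sequencing in 12 libraries of mouse bone marrow neutrophils, the short-lived phagocytes that are the first cells to reach a bacterial infection. Cells came from wild-type mice or from mice with a disrupted Cybb gene, called the knockout here. Cybb encodes the membrane subunit that transfers electrons in NOX2, the oxidase with which phagocytes make superoxide. The isolated cells were kept for 3 h with PBS or with CFT073, a uropathogenic strain of Escherichia coli (UPEC), at a multiplicity of infection of 100. This gave 4 groups of 3 libraries, with total gene counts from 27312527 to 34884314 per library. The question was how NOX2 shapes the inflammatory and antimicrobial programme of these cells. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

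The targeted gene was measured first. Cybb (ENSMUSG00000015340) lies on chromosome X of the mm10 build, from 9435252 to 9487771 on the minus strand. Its level was 1720 ± 15.1 CPM in wild-type PBS libraries, 1670 ± 30.4 CPM in wild-type UPEC libraries, 315 ± 11.1 CPM in knockout PBS libraries and 336 ± 11.6 CPM in knockout UPEC libraries (mean ± SD, n = 3 each). Each of the 6 knockout libraries lay below each of the 6 wild-type libraries. The knockout held 18.3% of the wild-type level with PBS and 20.1% with UPEC, a log2 difference of -2.45 ± 0.04 (SE) and -2.32 ± 0.04. These differences had adjusted p = 1.3e-20 and adjusted p = 3.77e-20 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts per gene do not show from which exons the remaining reads came. UPEC did not change Cybb detectably in either genotype, with a log2 change of -0.04 ± 0.04 in wild type and 0.09 ± 0.04 in the knockout. Cyba, which encodes the other membrane subunit of the oxidase, did not differ detectably between genotypes, at -0.08 with PBS and -0.13 with UPEC.

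**Figure D1:**
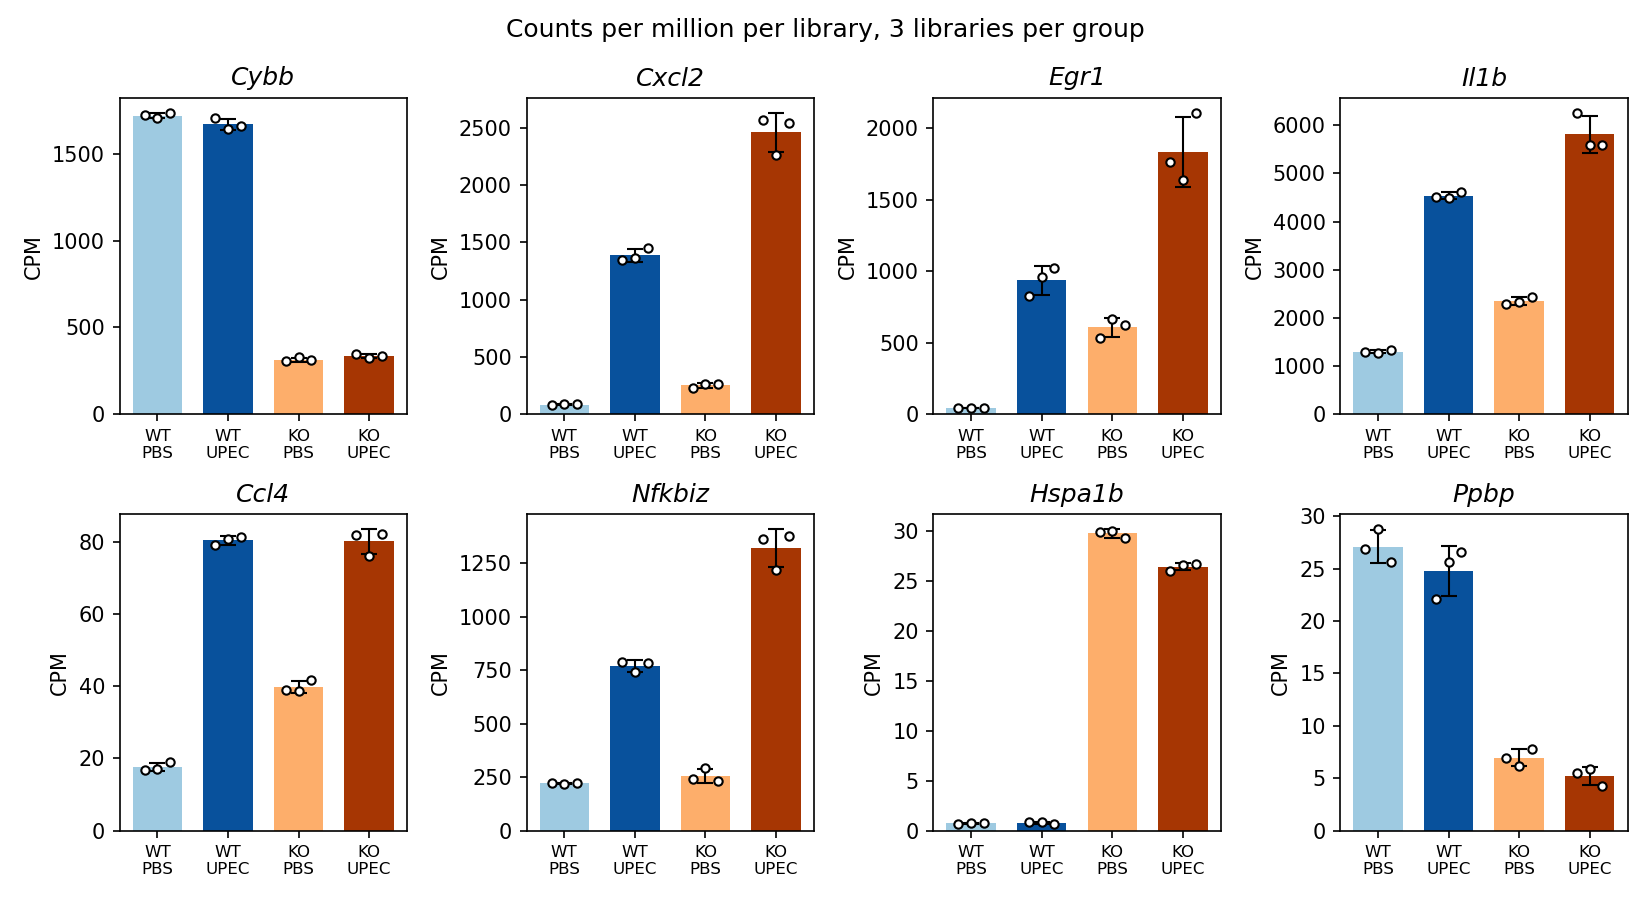
CPM of 8 genes in each of the 12 libraries; bars are group means, error bars are SD over n = 3 libraries and circles are single libraries. Cybb averaged 1720 and 1670 CPM in wild-type groups and 315 and 336 CPM in knockout groups, Cxcl2 went from 85 to 1390 CPM with UPEC in wild type and from 253 to 2460 CPM in the knockout, and Hspa1b stayed under 1 CPM in every wild-type library.

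Knockout PBS replicate 2 stood apart from its group. The chi-square of its counts per gene was 11.13 against replicate 1 and 17.28 against replicate 3. Replicates 1 and 3 gave 3.62, and pairs in the other 3 groups gave 2.08 to 6.57. Its share of reads outside annotated genes was 6.521%, against 4.674% and 4.295% in the other knockout PBS libraries. The highest share of all was 6.641%, in knockout UPEC replicate 3. No pair of libraries agreed within sampling noise, and each counted as 1 sample in the fits. Separately prepared libraries of 1 pool of cells could exceed that noise too, so this does not show that the samples are independent.

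The first comparison asked what 3 h with UPEC did to wild-type neutrophils. They switched on an early inflammatory programme of chemokines, cytokines and immediate-early transcription factors. Cxcl2, a chemokine that draws further neutrophils, rose 16.3-fold, from 85 ± 4.28 to 1390 ± 55.3 CPM (SD, n = 3; log2 4.03 ± 0.07 SE). Egr1, an immediate-early transcription factor, rose 21.1-fold and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, 15.5-fold. Il1b, which encodes interleukin-1 beta, rose 3.50-fold to 4540 ± 74.6 CPM, and transcripts of specific and gelatinase granule proteins, made earlier in neutrophil development, did not change detectably. In all, 1266 of 13587 genes changed, 653 upward and 613 downward, of which 145 changed at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

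Immediate-early genes formed the list with the highest median rise. Of 28 measured members 23 rose, 1 fell and 4 did not pass, or 23 and 2 adjusted over the list alone, with a median log2 change of 1.06. By camera, a test of a list against all other genes, adjusted p = 8e-40, and adjusted p = 0.01 with an estimated correlation. Its members include Egr1 at log2 4.40 ± 0.14, Egr3 at 3.20 ± 0.08, Egr2 at 3.01 ± 0.07 and Fos at 2.65 ± 0.08. Others are the mRNA-decay factor Zfp36 at 2.48 ± 0.05, the antiproliferative gene Btg2 at 2.00 ± 0.05 and the nuclear receptor Nr4a1 at 1.80 ± 0.05. Among 19 measured inflammatory cytokines 10 rose, none fell and 9 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.012 with an estimated correlation). Osm, a cytokine of the interleukin-6 family, rose by log2 2.67 ± 0.06 and Il1b by 1.81 ± 0.05. Tnf rose by 1.24 ± 0.05, Vegfa by 0.76 ± 0.05 and the interleukin-1 antagonist Il1rn by 0.34 ± 0.04. Il6 (0.03 ± 0.18) and Il10 (-0.89 ± 0.34) did not pass. Of 15 chemokine genes, with the decoy receptor Ccrl2 counted among them, 7 rose, 2 fell and 6 did not pass, the same counts adjusted over the list alone. Cxcl2, Cxcl1 (2.67 ± 0.26), Ccl4 (2.19 ± 0.05), Ccl3 (2.18 ± 0.05), Ccrl2 (2.18 ± 0.04) and Cxcl3 (1.85 ± 0.14) were among those that rose. Camera gave adjusted p = 8.5e-06 for chemokines, and adjusted p = 0.084 with an estimated correlation.

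NF-kB is a transcription factor of inflammatory genes. Of 27 measured genes of its pathway and its feedback 12 rose, 1 fell and 14 did not pass, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.6e-09, and adjusted p = 0.084 with an estimated correlation). Nfkbiz, Tnfaip3, Socs3 and Nfkbia, of which Tnfaip3 and Nfkbia inhibit NF-kB, rose by log2 1.80 ± 0.07, 1.18 ± 0.05, 0.99 ± 0.05 and 0.69 ± 0.05. The member that fell was Cd83, an activation marker also of dendritic and B cells, at -1.43 ± 0.16. Pattern-recognition receptors and adaptors rose in 12 of 25 cases, none fell and 13 did not pass, with 14 and 0 adjusted over the list alone (camera adjusted p = 2.1e-10, and adjusted p = 0.01 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 rose by 1.21 ± 0.05, Trem1 by 0.76 ± 0.04 and Tlr2 by 0.45 ± 0.04, and the inflammasome sensor Nlrp3 by 0.56 ± 0.06. Type I interferon-induced genes moved little. Of 32 measured 8 rose and 24 did not pass, 10 and 0 adjusted over the list alone, with a median of 0.10. Total counts in place of TMM scaling left 3 that rose and a median of 0.03. Camera gave adjusted p = 4.6e-05 for this list, and adjusted p = 0.0496 with an estimated correlation. None of 18 specific and gelatinase granule genes passed, among them Ltf at 0.02 ± 0.04 and Lcn2 at 0.02 ± 0.04. Of 10 azurophil granule genes Ctsc, whose protease activates the granule serine proteases, fell by 0.75 on the log2 scale, and Mpo (-0.13 ± 0.04) and Elane (-0.07 ± 0.05) did not pass.

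Among the genes with the steepest falls were Id3, an inhibitor of DNA binding (-1.74 ± 0.13), Emp1 (-1.67 ± 0.10), the purinergic receptor family member P2ry10b (-1.24 ± 0.12), the phosphatase Dusp3 (-1.0 ± 0.09), the glutathione-degrading enzyme Chac1 (-0.96 ± 0.10) and Gpr183, a receptor that guides lymphoid cells (-0.92 ± 0.07). The immunoglobulin segment Ighv5-17 fell by 1.11 on the log2 scale (adjusted p = 0.0392), a call that ended with any 1 of WT PBS replicates 1, 2 and 3, WT UPEC replicates 1 and 3, KO PBS replicate 1 or KO UPEC replicate 2 left out, with adjusted p between 0.0571 and 0.12. Markers of other cells moved alongside. Monocyte and macrophage markers fell in 9 of 20 cases and rose in 1 (camera adjusted p = 1.8e-05, and adjusted p = 0.0496 with an estimated correlation), among them Klf4 (-0.49 ± 0.05), which is also counted with the immediate-early genes, and the mannose receptor Mrc1 (-1.07 ± 0.20). Stromal and endothelial markers fell in 7 of 10 cases, among them Kdr at -2.00 ± 0.29 and the collagen gene Col1a1 at -0.48 ± 0.06, with a median of -0.45 (adjusted p = 8.5e-06, and adjusted p = 0.02 with an estimated correlation). Platelet and megakaryocyte markers fell in 2 of 11 cases, 4 adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.44 with an estimated correlation). None of 14 erythroid markers passed. With total counts in place of TMM scaling 384 genes rose and 1511 fell, and without KO PBS replicate 2, a library outside this comparison, 1969 genes changed. The count was 758 without WT PBS replicate 1, 826 without WT PBS replicate 3, 827 without WT UPEC replicate 1, 750 without WT UPEC replicate 3, and 2315 with only the 6 wild-type libraries in the fit.

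The second comparison asked the same of knockout neutrophils. UPEC raised the same kinds of genes there. Cxcl2 rose 9.72-fold, from 253 ± 22.6 to 2460 ± 168 CPM (SD, n = 3; log2 3.28 ± 0.07 SE). Ptgs2 rose by log2 2.76 ± 0.07, Il1a, the other agonist of the interleukin-1 receptor, by 2.67 ± 0.22, Osm by 2.65 ± 0.06, Zfp36 by 2.44 ± 0.05 and Nfkbiz by 2.38 ± 0.07. Il1b rose from 2350 ± 79.5 to 5810 ± 384 CPM. In all 1110 genes changed, 621 upward and 489 downward, and 120 at least 2-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

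Immediate-early genes rose in 24 of 28 cases and none fell, or 24 and 1 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 4.7e-33, and adjusted p = 0.01 with an estimated correlation). Fos rose by 1.89 ± 0.08, Nr4a1 by 1.71 ± 0.05, Ier3 by 1.61 ± 0.05 and Btg2 by 1.43 ± 0.05. Inflammatory cytokines rose in 9 of 19 cases, 1 fell and 9 did not pass, or 10 and 1 adjusted over the list alone (camera adjusted p = 3.4e-09, and adjusted p = 0.014 with an estimated correlation). Tnf stood at 1.57 ± 0.05, Il1b at 1.31 ± 0.05, Vegfa at 0.87 ± 0.05 and Il1rn at 0.45 ± 0.04. Il6 (0.46 ± 0.16) and Il10 (0.30 ± 0.34) did not pass. Chemokines rose in 6 of 15 cases and none fell, 7 and 0 adjusted over the list alone (camera adjusted p = 9.7e-06, and adjusted p = 0.086 with an estimated correlation). Cxcl1 stood at 2.28 ± 0.25, Ccl3 at 1.63 ± 0.05, Ccrl2 at 1.53 ± 0.04, Cxcl3 at 1.13 ± 0.11 and Ccl4 at 1.01 ± 0.05. Genes of the NF-kB pathway rose in 12 of 27 cases and none fell, 13 and 0 adjusted over the list alone (camera adjusted p = 3.1e-13, and adjusted p = 0.051 with an estimated correlation). Members that rose include Tnfaip3 (1.52 ± 0.05), the lymphocyte activation antigen Cd69 (1.36 ± 0.05) and the RNase gene Zc3h12a (1.08 ± 0.05). Pattern-recognition receptors rose in 7 of 25 cases and none fell, the same adjusted over the list alone, with Cd14 at 1.53 ± 0.05 (camera adjusted p = 7.7e-05, and adjusted p = 0.051 with an estimated correlation). Their median of 0.09 turned to -0.01 with total counts. Of 32 interferon-induced genes 2 rose, 3 fell and 27 did not pass, 2 and 6 adjusted over the list alone (camera adjusted p = 0.28). With total counts none rose and 12 fell, and their median of -0.02 became -0.12. Specific and gelatinase granule genes rose in 4 of 18 cases, 8 adjusted over the list alone, and none passed with total counts (camera adjusted p = 7.9e-05, and adjusted p = 0.22 with an estimated correlation). G0s2, an inhibitor of lipolysis, rose by 1.82 ± 0.07. Txnip, which binds thioredoxin and limits glucose uptake, fell by 1.12 on the log2 scale, and Rhov (-0.96 ± 0.12) and Emp1 (-0.91 ± 0.11) fell too.

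In the knockout, transcripts of several other cell types fell with UPEC beside these groups. Erythroid markers fell in 11 of 14 cases, 14 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 8.8e-12, and adjusted p = 0.086 with an estimated correlation). Hba-a2, a haemoglobin gene, stood at -0.32 ± 0.05. Stromal and endothelial markers fell in 6 of 10 cases, 8 adjusted over the list alone, with a median of -0.76 (adjusted p = 3.4e-09, and adjusted p = 0.01 with an estimated correlation). B-lineage markers fell in 5 of 14 (adjusted p = 2.9e-06, and adjusted p = 0.056 with an estimated correlation), among them Igkc at -0.60 ± 0.07. Platelet and megakaryocyte markers fell in 3 of 11 cases, 5 adjusted over the list alone, with a median of -0.33 (adjusted p = 0.00082, and adjusted p = 0.18 with an estimated correlation). The immunoglobulin segments Igkv4-55, Ighv1-18, Igkv14-111, Igkv12-44 and Igkv8-27 fell by 1.12, 1.02, 1.00, 0.99 and 0.93 on the log2 scale, and as members of large families of similar segments their counts are uncertain. The call of Igkv4-55 ended without KO PBS replicate 1 or 3 or KO UPEC replicate 3 (adjusted p up to 0.0721), and that of Igkv14-111 without KO PBS replicate 3 or KO UPEC replicate 1 or 2 (adjusted p up to 0.0753). Total counts in place of TMM scaling called 2711 genes, 317 upward and 2394 downward, and the 6 knockout libraries fitted alone called 648. The count was 2466 without KO PBS replicate 2, 711 without KO PBS replicate 1, 690 without KO UPEC replicate 1 and 729 without KO UPEC replicate 3.

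The responses of both genotypes pointed largely the same way. Of the genes called in each, 267 rose in both, against 29.8 for independent lists of these sizes, 153 fell in both against 22.1, and 16 went opposite ways. These comparisons share no libraries. Across all 13587 genes, which are not independent replicates, Pearson's r between the log2 changes was 0.456 and Spearman's rho 0.31. Over the 1940 genes called in either genotype r was 0.734, but these were chosen by the same log2 changes, which can itself raise r.

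**Figure D2:**
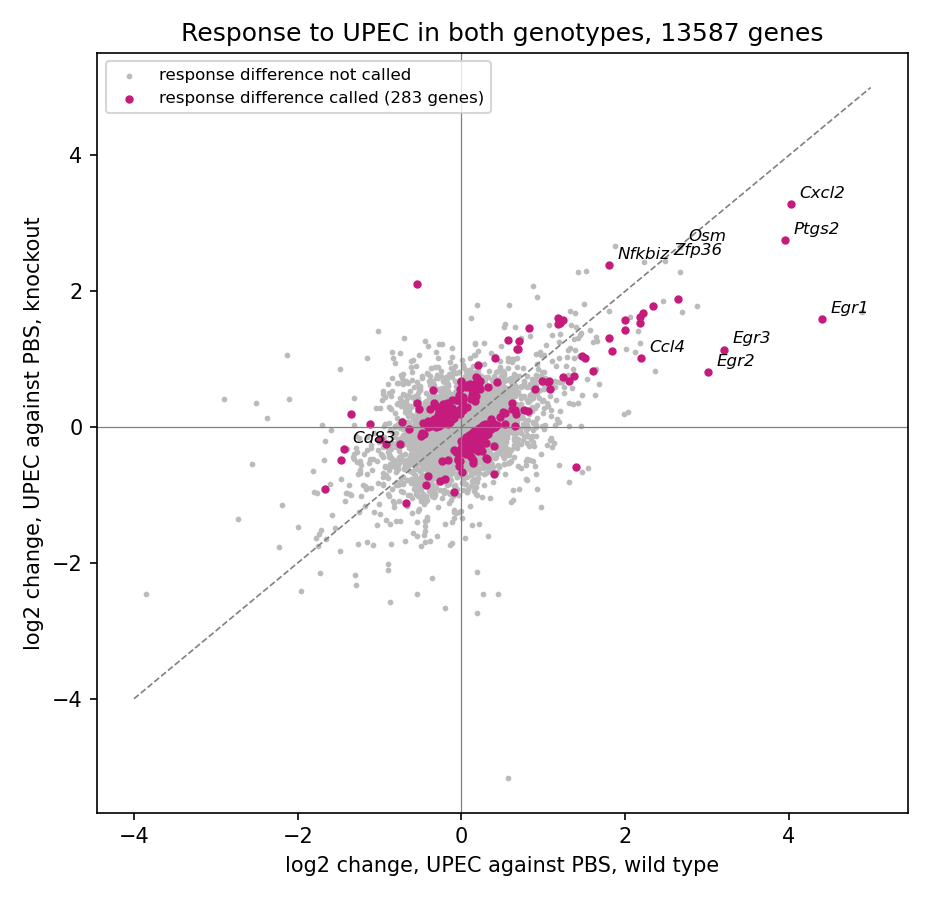
Log2 change with UPEC in wild type (horizontal axis) against the knockout (vertical axis), a point per tested gene; the dashed line marks equal change and coloured points are the 283 genes whose responses differed. Egr1, Egr2 and Egr3 lie far under the line, at 4.40, 3.01 and 3.20 in wild type, while Zfp36 and Osm lie close to it.

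The third comparison asked how knockout neutrophils differed from wild type before any contact with bacteria, whether through loss of NOX2 or otherwise. With PBS alone, knockout neutrophils already carried higher levels of many genes that UPEC raised in wild-type cells. Both comparisons use the same wild-type PBS libraries, so part or all of this overlap may come from them. Cxcl2 was higher by log2 1.58 ± 0.07, Ptgs2 by 1.83 ± 0.07, Cxcl3 by 1.46 ± 0.14, Ccl4 by 1.18 ± 0.05 and Il1b by 0.86 ± 0.05. Egr1 averaged 608 ± 69.1 CPM against 44.3 ± 2.13 in wild type (SD, n = 3; log2 3.78 ± 0.13 SE), and Egr3 and Egr2 were higher by 3.26 ± 0.08 and 2.31 ± 0.07. Hspa1b and Hspa1a, which encode inducible heat shock proteins of the HSP70 family, were higher by 5.36 ± 0.09 and 5.26 ± 0.15, the largest rises under the naming rule. In all 1950 genes differed, 1082 higher and 868 lower in the knockout, and 285 at least 2-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

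Immediate-early genes were higher in 25 of 28 cases and lower in 2, the same adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.8e-27, and adjusted p = 0.014 with an estimated correlation). Btg2 at 1.42 ± 0.05 and the phosphatase Dusp5 at 1.23 ± 0.04 were among them. Type I interferon-induced genes were higher in 22 of 32 cases, lower in 1 and did not pass in 9, or 23 and 1 adjusted over the list alone (camera adjusted p = 2.1e-14, and adjusted p = 0.012 with an estimated correlation). Rtp4 was higher by 1.01 ± 0.05, the oligoadenylate synthetase Oas1a by 0.98 ± 0.06, Oasl1 by 0.89 ± 0.06 and the antiviral gene Rsad2 by 0.79 ± 0.04. Heat shock and chaperone genes were higher in 11 of 14 cases and lower in none, the same adjusted over the list alone (camera adjusted p = 3.6e-10, and adjusted p = 0.014 with an estimated correlation). Hsph1 stood at 0.60 ± 0.06 and Dnaja1 at 0.45 ± 0.04. Hspa1a and Hspa1b lie side by side on chromosome 17 (34969190 to 34972156 and 34956436 to 34959238, mm10) and are near-identical, so how reads divided between them is uncertain. Pattern-recognition receptors were higher in 13 of 25 cases and lower in none, or 14 and 0 adjusted over the list alone, with Trem1 at 0.92 ± 0.04, Cd14 at 0.71 ± 0.05 and Clec4d at 0.65 ± 0.04 (camera adjusted p = 4.8e-06, and adjusted p = 0.024 with an estimated correlation). Nlrp3 was higher by 0.78 ± 0.06. Cytokines were higher in 5 of 19 cases and lower in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.081 with an estimated correlation). Chemokines were higher in 7 of 15 and lower in 2, the same adjusted over the list alone (adjusted p = 0.0034, and adjusted p = 0.23 with an estimated correlation). Tnf did not differ detectably at 0.07 ± 0.05, and the inhibitor Nfkbia was lower, at -0.32 ± 0.05.

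The knockout PBS libraries also differed from wild type in transcripts of other cells. All 11 platelet and megakaryocyte markers were lower, with a median of -1.13 (camera adjusted p = 2.1e-14, and adjusted p = 0.019 with an estimated correlation). Among them was the platelet chemokine gene Ppbp at -1.96 ± 0.10, and Alox12, the platelet lipoxygenase, was lower by -1.98 ± 0.14. All 14 erythroid markers were higher, with a median of 0.36 (adjusted p = 1.6e-13, and adjusted p = 0.052 with an estimated correlation). B-lineage markers were higher in 11 of 14 cases and lower in 1, with a median of 0.64 (adjusted p = 1.4e-06, and adjusted p = 0.038 with an estimated correlation). The member that was lower, Ighm at -1.0 ± 0.06, is the heavy chain of immunoglobulin M, and the summed level of the list was 2810 ± 103 CPM against 3350 ± 12.8 CPM in wild type (SD, n = 3). Stromal and endothelial markers were lower in 4 of 10 cases, with Cxcl12, a chemokine of marrow stroma, at -1.53 ± 0.06 (adjusted p = 0.00069, and adjusted p = 0.038 with an estimated correlation). T and NK cell markers were higher in 2 of 10 cases, 5 adjusted over the list alone, with a median of 0.64 (adjusted p = 0.0027, and adjusted p = 0.079 with an estimated correlation). Monocyte and macrophage markers were lower in 6 of 20 cases and higher in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.19 with an estimated correlation). Of the 16 genes named for the largest differences, 8 were immunoglobulin segments. Ighv1-5 (3.56 ± 0.35), Igkv2-137 (2.68 ± 0.24) and Ighv1-81 (2.44 ± 0.13) were higher, and Igkv1-88 (-2.86 ± 0.20), Ighv5-16 (-2.75 ± 0.24), Ighv1-80 (-2.54 ± 0.11), Igkv3-4 (-2.22 ± 0.37) and Igkv4-55 (-2.04 ± 0.17) were lower, with counts that are uncertain for the reason given above. With total counts in place of TMM scaling 36.6% of the calls were higher in the knockout, against 55.5%.

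The fourth comparison set the genotypes side by side after UPEC. Many of the differences seen with PBS were called here too, while those of some lists were not. Hspa1b and Hspa1a were higher in the knockout by log2 5.09 ± 0.10 and 4.59 ± 0.15, the immediate-early genes Nr4a3 and Fosl1 by 3.03 ± 0.18 and 2.28 ± 0.07, Cxcl2 by 0.83 ± 0.06, Nfkbiz by 0.78 ± 0.07, Il6 by 0.74 ± 0.17 and Ptgs2 by 0.64 ± 0.06. Tnf was higher by 0.41 ± 0.04 and Il1b by 0.36 ± 0.04, while Ccl4 (-0.01 ± 0.05), Ccl3 (-0.11 ± 0.05) and Cxcl1 (0.01 ± 0.19) did not differ detectably. In all 2746 genes differed, 1529 higher and 1217 lower, and 318 at least 2-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of genes called with each treatment 641 were higher in both, against 121.8 for independent lists, 505 lower in both against 77.7, and 19 differed in opposite directions. These 2 comparisons share no libraries.

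Immediate-early genes were higher in 20 of 28 cases, lower in 3 and did not pass in 5, or 23 and 3 adjusted over the list alone (camera adjusted p = 4.7e-13, and adjusted p = 0.065 with an estimated correlation). Egr3 stood at 1.2 ± 0.06 and Nr4a1 at 1.18 ± 0.05. Interferon-induced genes were higher in 18 of 32 cases and lower in 2, or 20 and 2 adjusted over the list alone, with Oas1a at 0.99 ± 0.06 and Irf7, the master regulator of interferon genes, at 0.52 ± 0.04, while Irf1 was lower at -0.80 ± 0.04 (camera adjusted p = 5.1e-07, and adjusted p = 0.032 with an estimated correlation). Heat shock and chaperone genes were higher in 12 of 14 cases, the same adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.032 with an estimated correlation). Cytokines were higher in 10 of 19 cases and lower in 1, or 10 and 2 adjusted over the list alone, the lower one being Tnfsf14 at -0.68 ± 0.04 (camera adjusted p = 0.0055, and adjusted p = 0.15 with an estimated correlation). NF-kB pathway genes were higher in 12 of 27 cases and lower in 3, or 14 and 4 adjusted over the list alone, with Cd69 at 1.09 ± 0.05 and Tnfaip3 at 0.53 ± 0.05 (camera adjusted p = 0.0028, and adjusted p = 0.37 with an estimated correlation). Pattern-recognition receptors were higher in 10 of 25 cases and lower in 3, or 10 and 4 adjusted over the list alone, with a median of 0.06 that turned to -0.02 with total counts (camera adjusted p = 0.034, and adjusted p = 0.23 with an estimated correlation). Chemokines were higher in 5 of 15 cases and lower in 1, or 5 and 2 adjusted over the list alone, with a median of 0.02 that turned to -0.06 with total counts (camera adjusted p = 0.47). Among azurophil granule genes 5 of 10 were higher, or 7 adjusted over the list alone, with Mpo, the peroxidase that turns hydrogen peroxide into hypochlorous acid, at 0.40 ± 0.04 and the elastase gene Elane at 0.29 ± 0.05 (camera adjusted p = 0.0096, and adjusted p = 0.49 with an estimated correlation). Mpo and Elane were also called higher in the knockout with PBS, at 0.25 and 0.2. That call of Elane ended without KO PBS replicate 1.

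All 11 platelet markers were lower again, with a median of -1.2 (camera adjusted p = 4.7e-13, and adjusted p = 0.032 with an estimated correlation). They include Ppbp at -2.24 ± 0.10 and the platelet tubulin Tubb1 at -2.25 ± 0.14, and Alox12 was at -2.40 ± 0.16. Stromal and endothelial markers were lower in 6 of 10 cases, with Cxcl12 at -2.05 ± 0.06 (adjusted p = 5.5e-06, and adjusted p = 0.032 with an estimated correlation). Basophil and mast cell markers were higher in 5 of 9, with the histidine decarboxylase gene Hdc at 0.86 ± 0.07 (adjusted p = 0.006, and adjusted p = 0.066 with an estimated correlation). T and NK cell markers were higher in 4 of 10, the same adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0073, and adjusted p = 0.15 with an estimated correlation). Erythroid markers were higher in 3 of 14, the same adjusted over the list alone, with a median of 0.05 that turned to -0.02 with total counts (adjusted p = 0.25). B-lineage markers were higher in 5 of 14 and lower in 2, or 6 and 2 adjusted over the list alone (adjusted p = 0.051). The immunoglobulin segments Ighv4-1 (2.68 ± 0.15), Ighv1-81 (2.59 ± 0.15), Igkv13-84 (2.25 ± 0.29) and Igkv4-86 (2.12 ± 0.22) were higher, and Igkv1-88 (-3.75 ± 0.23), Ighv5-16 (-2.98 ± 0.27), Ighv1-80 (-2.75 ± 0.13) and Igkv4-55 (-2.33 ± 0.21) were lower, again with uncertain counts. With total counts 25.3% of the calls were higher in the knockout, against 55.7%.

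**Figure D3:**
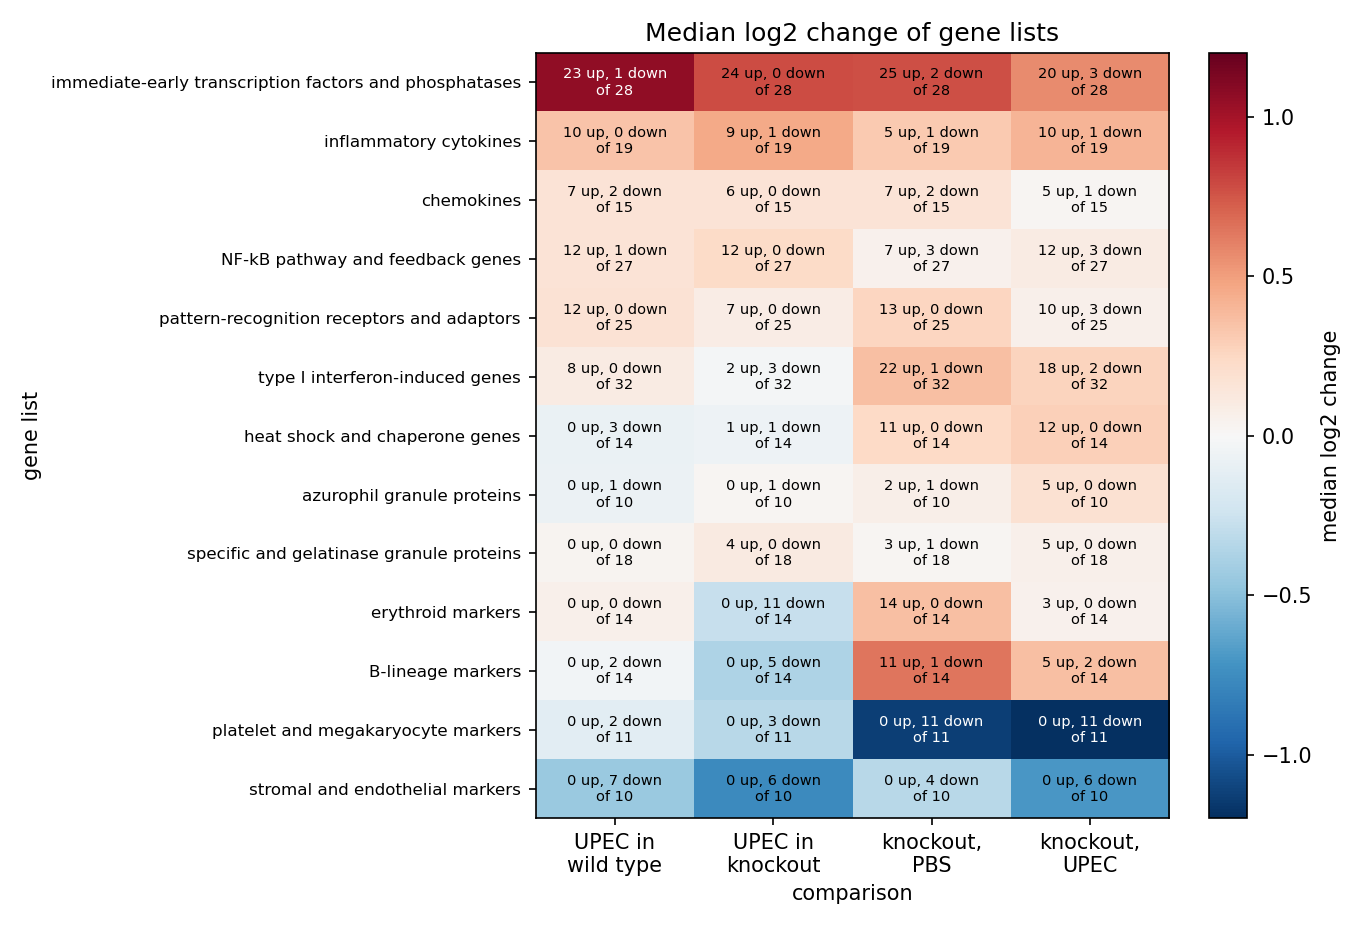
Median log2 change of 13 gene lists (vertical axis) in 4 comparisons (horizontal axis), coloured from -1.2 (blue) to 1.2 (red), with the numbers of members called up and down; with total counts in place of TMM scaling the medians of pattern-recognition receptors (knockout response, genotypes with UPEC), azurophil granule genes (knockout response), specific and gelatinase granule genes (wild-type response, genotypes with either treatment), and chemokines and erythroid markers (genotypes with UPEC) turned negative. Immediate-early genes had medians of 1.06, 0.78, 0.77 and 0.57 from left to right, and platelet and megakaryocyte markers were lower in the knockout at -1.13 with PBS and -1.2 with UPEC.

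The last comparison asked whether UPEC changed genes by different amounts in the genotypes, as an interaction of genotype and treatment. The early-growth-response genes rose by a smaller fold in the knockout, which started higher. Egr1 went from 44.3 ± 2.13 to 936 ± 100 CPM in wild type and from 608 ± 69.1 to 1840 ± 244 CPM in the knockout (SD, n = 3). A smaller log2 response is a smaller ratio, and need not be a smaller rise in CPM. The response of Egr1 was smaller by 2.81 ± 0.17 on the log2 scale (written -2.81 where the knockout response is the smaller), that of Egr2 stood at -2.20 ± 0.09, Egr3 at -2.06 ± 0.11, Ptgs2 at -1.19 ± 0.09 and Ccl4 at -1.18 ± 0.07. Ccl4 went from 17.6 ± 1.11 to 80.5 ± 1.26 CPM in wild type and from 39.8 ± 1.73 to 80.2 ± 3.38 CPM in the knockout (SD, n = 3). Other genes rose more in the knockout, such as Nfkbiz (0.58 ± 0.10), Nfkbia (0.46 ± 0.06), Tnf (0.34 ± 0.07) and Tnfaip3 (0.34 ± 0.07). In all 283 genes differed, 124 with a more positive and 159 with a more negative change in the knockout, and 11 by at least 2-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

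Of 28 immediate-early genes 14 had a more negative response in the knockout, 2 a more positive one and 12 did not pass, or 16 and 4 adjusted over the list alone (camera adjusted p = 1.5e-10, and adjusted p = 0.18 with an estimated correlation). Dusp5 stood at -0.64 ± 0.06 and Atf3 at -0.51 ± 0.05. Chemokines were more negative in 5 of 15 cases, the same adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.26 with an estimated correlation), namely Ccl4, Cxcl2 (-0.75 ± 0.09), Cxcl3 (-0.72 ± 0.18), Ccrl2 (-0.66 ± 0.06) and Ccl3 (-0.55 ± 0.07). Il1b stood at -0.50 ± 0.06, and Il6 (0.43 ± 0.24), Cxcl1 (-0.38 ± 0.40), Nlrp3 (-0.03 ± 0.08) and Mpo (0.15 ± 0.06) did not pass. Interferon-induced genes were more negative in 4 of 32 cases, 10 adjusted over the list alone (camera adjusted p = 6.7e-06, and adjusted p = 0.18 with an estimated correlation). The kinase gene Plk2 (-0.78 ± 0.08), the cytokine-signalling inhibitor Socs1 (-0.78 ± 0.16) and Rhov (-0.86 ± 0.17) were also more negative. More positive were Cd83 (1.10 ± 0.22), P2ry10 (0.89 ± 0.16), Dusp3 (0.83 ± 0.13), Emp1 (0.76 ± 0.15), the laminin gene Lamb3 (0.71 ± 0.12), the hyaluronan-binding Tnfaip6 (0.70 ± 0.13), Suco (0.68 ± 0.14) and Arl5b (0.68 ± 0.11). Of the 159 genes with a more negative change, 85 rose in wild type, 35 rose in both genotypes and 79 fell in the knockout, by tests on the libraries that also make up the interaction.

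Erythroid markers moved with this difference, with 9 of 14 more negative in the knockout, 14 adjusted over the list alone, and a median of -0.34 (camera adjusted p = 1.6e-14, and adjusted p = 0.18 with an estimated correlation). Left out singly, libraries moved the count to 171 (WT PBS replicate 1), 188 (WT PBS replicate 3), 176 (WT UPEC replicate 2), 171 (WT UPEC replicate 3) and 762 (KO PBS replicate 2). They ended the calls of Cd83 (KO UPEC replicate 1, adjusted p = 0.0506), Cxcl3 (WT PBS replicates 1 and 2, WT UPEC replicates 1, 2 and 3, KO PBS replicate 3 and KO UPEC replicate 2, adjusted p up to 0.161) and Suco (WT PBS replicates 1 and 3, WT UPEC replicates 2 and 3, and replicates 1 and 3 of both knockout groups, adjusted p up to 0.0812). Total counts also ended the call of Suco (adjusted p = 0.0502), and with them 26.1% of the calls were more positive, against 43.8%.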

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

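The counts over other splits and the test of library scaling were planned, and the tests of a lower neutrophil share and of handling were chosen only after the result was seen. Each result in this part stands here because a test of the interaction found that the response to UPEC differed between the genotypes.

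The responses differed for 283 genes. Left out singly, WT PBS replicate 1 moved this to 171, WT PBS replicate 3 to 188, WT UPEC replicate 2 to 176, WT UPEC replicate 3 to 171 and KO PBS replicate 2 to 762. Of 100 regroupings drawn from 200 possible ones, 6 called as many genes, the real one included, which does not exclude chance. The 5 others, with 468 to 3757 genes, each joined the UPEC libraries of 1 genotype with 2 or 3 PBS libraries of the other. This turns the genotype difference into a response difference and points to the structure of the samples, so the count gives no evidence for chance either.

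Most immediate-early genes were higher in knockout libraries with PBS, and with UPEC 14 of 28 had a more negative response in the knockout, 2 a more positive one and 12 did not pass. The list median was -0.24 for the response difference (camera adjusted p = 1.5e-10, a call lost with an estimated correlation at adjusted p = 0.18), with single values of -2.81 (Egr1), -2.2 (Egr2), -2.06 (Egr3), -0.64 (Dusp5) and -0.51 (Atf3). Scaling as the cause of the higher levels with PBS is argued against, as far as the choice between TMM and total counts goes. Under total counts alone 24 of 28 members were called higher with PBS. That choice shifts this comparison by only -0.04 on the log2 scale, so the outcome could hardly change. The response difference was not part of this test. A lower share of neutrophils with every other cell type raised alike is argued against. With PBS platelet markers had a median of -1.13, while B-lineage and erythroid markers had 0.64 and 0.36. Other cell types can vary separately, so a changed mix of cells stays open. A handling difference between preparations may have raised the immediate-early genes before any treatment, and 11 of 14 heat shock and chaperone genes were higher with PBS as well. The labels do not say how the preparations were divided over animals or days, so a handling difference and an effect of NOX2 loss cannot be told apart.

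Among other genes of the inflammatory programme the response difference was -1.19 for Ptgs2, -1.18 for Ccl4, -0.75 for Cxcl2, -0.72 for Cxcl3, -0.66 for Ccrl2, -0.55 for Ccl3 and -0.5 for Il1b, and 0.58 for Nfkbiz, 0.46 for Nfkbia and 0.34 for both Tnf and Tnfaip3. It was 1.1 for Cd83, 0.89 for P2ry10, 0.83 for Dusp3, 0.76 for Emp1, 0.71 for Lamb3, 0.7 for Tnfaip6 and 0.68 for both Suco and Arl5b. It was -0.86 for Rhov and -0.78 for both Plk2 and Socs1, and among genes outside the lists described in the results 0.68 for Cdkn1a, -0.49 for Cxcr4, -0.43 for Ppp1r15a and -0.41 for Osgin1. Lists whose response differed by camera had medians of -0.14 (chemokines), -0.09 (interferon-induced genes), -0.13 (p53 targets), -0.29 (B-lineage markers), -0.34 (erythroid markers), 0.09 (azurophil granule proteins), 0.1 (specific and gelatinase granule proteins) and 0.13 (monocyte and macrophage markers), and each of these calls was lost with an estimated correlation. The call of Cd83 ended without KO UPEC replicate 1 (adjusted p = 0.0506) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That of Cxcl3 ended without WT PBS replicate 1 or 2, any WT UPEC replicate, KO PBS replicate 3 or KO UPEC replicate 2 (adjusted p up to 0.161). That of Suco ended without replicate 1 or 3 of WT PBS, KO PBS or KO UPEC, or WT UPEC replicate 2 or 3 (adjusted p up to 0.0812), and with total counts (adjusted p = 0.0502).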

How the results depend on the processing

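Fits without KO PBS replicate 2 and KO UPEC replicate 3, the libraries with the most unassigned reads, and counts without immunoglobulin and other-cell genes were chosen after seeing the data. The cause of the changes was not tested, except that a fold minimum calls fewer genes by construction. A 2-fold minimum left 145 and 120 genes in the wild-type and knockout responses, 285 and 318 between genotypes with PBS and UPEC, and 11 in the interaction, and glmTreat left 219, 226, 495, 576 and 23. Total counts called 2711 in the knockout response, and no filter on low counts 477 in the interaction. The replicate block nested in genotype gave 822 in the wild-type response and 157 in the interaction, and the additive replicate block gave 1049, 913, 1747, 2425 and 225. Correlations of same-numbered libraries, with group means removed, ran from -0.124 to 0.074, which shows no strong effect shared by a number. With 3 libraries per group they cannot exclude that the numbers mark shared animals or days. Numbers were taken from the sample titles, and that of KO UPEC replicate 3 differs from the number in its deposited name. Its pairing in this check and in the block fits is therefore uncertain. Fits of 6 libraries alone gave 2315 and 648 for the responses. Without both doubted libraries the responses gave 2102 and 1755 and the interaction 563. Each library left out in turn gave 750 to 1969 in the wild-type response, 690 to 2466 in the knockout response and 171 to 762 in the interaction. The correlation of both responses, 0.456, was 0.593 at 1 CPM or more and 0.378 to 0.435 with a library left out. Over genes called in either, which were chosen by the same changes, it was 0.734. The 260 values of genes selected by the naming rule had 6557 alternative values, of which 6261 kept direction and call, 209 lost the call, 37 gained one and 50 changed sign without a call under either setting. The sign of a called value changed in 0. Some of these outcomes were fixed in advance. The 225 values without immunoglobulin and other-cell genes are those of the main fit, and the 260 under the 2-fold minimum could not change direction. A further 3120 came from single libraries left out, among them libraries outside the comparison. Of 185 list tests 82 were called, and 56 of these lost their call with an estimated correlation, all 9 in the interaction among them. In simulated counts of this depth 28% of 1.2-fold differences in the response were recovered. Lipid mediator synthesis pointed the other way by fry between genotypes with PBS (adjusted p = 0.0447), and cytosolic ribosomal proteins did so in the interaction without KO PBS replicate 2 (adjusted p = 0.0143, over single libraries left out up to 0.905).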

Other observations

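The tests on immunoglobulin genes, on the heat shock list and on reads moved between copies were chosen only after the result was seen, and those on chromosomal neighbours and shared controls were planned.

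Single genes that answer oxidative stress differed, while their list as a whole was not called with either treatment. With PBS, Srxn1, which repairs oxidised peroxiredoxins, was higher in the knockout by log2 0.83 ± 0.09, the cystine transporter Slc7a11 by 1.01 ± 0.1 and the ferritin gene Fth1 by 0.39 ± 0.04, and Osgin1 stood at -0.3 ± 0.05. With UPEC, Srxn1 was higher by 1.14 ± 0.08 and Fth1 by 0.51 ± 0.04, and Osgin1 stood at -0.72 ± 0.06. Over the whole list of 28 NRF2 targets and antioxidant enzymes 7 were higher and 3 lower with PBS, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.22), and the median of 0.01 turned to -0.03 with total counts. With UPEC 6 were higher and 4 lower, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.57), and the median of 0.02 turned to -0.06. Of 20 genes of the unfolded protein and integrated stress response 6 were higher and 1 lower with PBS, the same adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.36 with an estimated correlation), among them Ppp1r15a at 0.67 ± 0.05, Dnajb9 at 0.39 ± 0.04 and the endoplasmic reticulum chaperone Hspa5 at 0.31 ± 0.04. With UPEC 7 were higher and 2 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.46 with an estimated correlation).

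Of 17 p53 targets 8 were higher and none lower with PBS, or 8 and 1 adjusted over the list alone (camera adjusted p = 6.9e-06, and adjusted p = 0.019 with an estimated correlation), with Plk2 at 0.98 ± 0.06 and Gadd45a at 0.55 ± 0.04. With UPEC 9 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.15 with an estimated correlation). There the cell cycle inhibitor Cdkn1a was higher by 0.89 ± 0.05, and the chemokine receptor Cxcr4, which retains neutrophils in marrow, stood at -0.69 ± 0.04. Acod1, the enzyme that makes itaconate, was higher by 1.13 ± 0.1 with PBS and 0.87 ± 0.1 with UPEC. Replication-dependent histones were higher in 4 of 13 cases with PBS, 5 adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.039 with an estimated correlation), and dendritic cell markers in 6 of 15 with 1 lower, the same adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.032 with an estimated correlation). With UPEC neither list was called, with 1 of 13 histones higher (camera adjusted p = 0.087) and 2 of 15 dendritic cell markers (camera adjusted p = 0.052).

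Immunoglobulin variable genes differed between genotypes more than within groups, with 55 higher and 18 lower of 166 tested with PBS, and their genotype differences with PBS and with UPEC correlated at 0.87 across genes, which are not independent replicates. A variant at 1 locus is argued against, since 42.5% of heavy chain and 44.7% of kappa genes were called, against 14.4% of all genes. A different share of B-lineage cells may account for part of it, and stays open because 24.7% of the called variable genes moved in the less frequent direction. That each genotype's libraries came from 1 shared pool of cells stays open. The spread of variable genes within groups was 2.23 times that of genes of like mean, but aliquots of a pool with few B-lineage cells would spread too, so a wide spread, first taken to exclude a pool, decides nothing. Different antibody repertoires of the mice were not tested.

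Hspa1a and Hspa1b were far higher in knockout libraries with either treatment. Reads moved from 1 copy to the other are argued against, since the summed CPM of both was 40.1-fold higher with PBS and 29.8-fold with UPEC. A broad heat shock response in the knockout preparation would raise the other list members too. With PBS 9 of 12 were higher, 75% against 8% of all genes, though their median was 0.23. Fisher's exact test, two-sided, gave p = 2.2e-08, but it treats genes as independent, which genes measured in the same libraries are not. A strain segment on chromosome 17 stays open, with 19 of 91 genes within 1 Mb called, 20.9% against 14.4% (Fisher's exact test, two-sided, p = 0.096). An effect of NOX2 loss itself was not tested apart from the preparation, whose division over animals or days the labels do not give.

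A strain segment around the targeted gene was tested on its neighbours. Of 50 genes within 5 Mb of Cybb 5 were called with both treatments, 10% against 8.4% of all genes (Fisher's exact test, two-sided, p = 0.61), which leaves it open. With PBS and UPEC they stood at 2.85 and 2.45 (Gm6829, a pseudogene at 0.125 CPM in wild type and 0.9204 CPM in the knockout with PBS), 0.44 and 0.47 (Ddx3x), 0.20 in both (Ftsj1), -0.20 and -0.14 (Rbm3) and -0.20 and -0.24 (Mid1ip1), named after their values were seen.

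Knockout libraries with PBS may resemble wild-type libraries with UPEC. Of genes called in both comparisons against wild-type PBS, 322 were higher in both, against 52 for independent lists, 197 lower in both against 39.2, and 39 opposite. Both comparisons share the 3 wild-type PBS libraries, which alone makes them covary. The covariance was 0.0492, above the highest of 20 simulations without any effect (0.019). This argues against independent noise of the shared libraries as the whole cause. The simulations held no deviation common to all 3 wild-type PBS libraries, so they cannot exclude one as the cause. The correlation of 0.411 lay under the simulated mean of 0.49, and part or all of the overlap may come from the shared libraries.

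The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. The real counts were 1266, 1110, 1950 and 2746, and the highest others were 0, 866, 1 and 0, for the wild-type response, the knockout response and the genotypes with PBS and UPEC. The split with 866 genes put KO PBS replicate 2 with KO UPEC replicates 1 and 3. KO UPEC replicate 2 joined KO PBS replicates 1 and 3 in it. Reads outside annotated genes made up 6.521%, 5.814% and 6.641% in the first set and 5.547%, 4.674% and 4.295% in the other. This share averaged 4.72% and 5.37% in wild type with PBS and UPEC, and 5.16% and 6% in the knockout. No fit took it into account as a covariate.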
